A study of Frankliniella occidentalis and Frankliniella intonsa with 9 samples.

How the data were processed

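RNA from antennae of 1 day old adult thrips was sequenced in 9 libraries: 3 of female and 3 of male Frankliniella occidentalis and 3 of female Frankliniella intonsa. Per the labels' protocols, cDNA was made from low amounts of total RNA by SMARTer template switching and amplified by PCR before library construction. Per the submitters' processing notes, cutadapt, FastQC and Salmon were used, with no versions given. The assembler, its version and the annotation release are not given in the sources used here. The authors deposited 1 table of TPM for 48889 genes of an assembly that holds transcripts of both species, with annotation text from several databases. The unit is not written in the table and was taken from the column totals (935518 to 987791) and from Salmon, which reports TPM. The smallest row maximum was 5.01, so genes that stayed low in every library are absent. No read numbers are held, so depth and counting error are unknown. All 9 value columns were matched to samples by name and 0 were left without a sample. No genome was used, and 0 of the gene identifiers matched the RefSeq gene table, so names come from the annotation text of the table.

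The design fixed before the data were examined named a count test for counts and limma-trend for a normalized unit. Since the table holds TPM, limma-trend (limma 3.58.1, R 4.3.3) on log2(TPM + 1) was used, with a TPM of at least 1 in at least 3 libraries of the comparison and a Benjamini-Hochberg adjusted p threshold of 0.05. A fold change on this scale understates the change of low genes. The sex comparison used the 6 F. occidentalis libraries (positive is higher in males), and the species comparison the 6 female libraries (positive is higher in F. intonsa). Neither used a covariate. Tables and exact tests were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and statsmodels 0.14.6, and plots with matplotlib 3.10.9.

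Also fixed before the data were examined were 26 gene lists by annotation wording: OBPs, CSPs, odorant, ionotropic and gustatory receptors, sensory neuron membrane proteins, cytochromes P450, carboxylesterases, glutathione S-transferases, UDP-glycosyltransferases, ABC transporters, takeout and juvenile hormone binding genes, cuticle proteins, ribosomal proteins, oxidative phosphorylation, heat shock proteins, neuronal, axonemal and sperm, eye, muscle, fat body, ovary, gut and salivary gland, immune and sex determination genes, and microbial and viral matches. Wording does not prove identity: 1 gene of the OBP list matched acetylcholinesterase in Swiss-Prot, and 2 genes of the CSP list matched sensory neuron membrane protein 2. Each list was tested two-sided with camera (limma) at a preset correlation of 0.01, adjusted over the 26 lists of a comparison, and again with an estimated correlation. The share of each library's TPM in OBPs and in CSPs was compared with an exact two-sided permutation test, whose smallest p for 3 against 3 is 0.1. Lists of genes by matched organism (microsporidian, pig, bacterial and plant) were written after the data were seen.

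The named genes follow a rule fixed before the data were examined. In each comparison it takes the 10 largest rises and 10 largest falls among genes past the threshold with an informative product name, non-overlapping groups and a mean of at least 1 TPM in both groups, with 1 gene per annotation text. It adds the called OBP and CSP genes up to 10 per list, the 5 genes of highest mean in each of these lists, and up to 4 called genes of each other list. Genes at 0 in all libraries of one group with a mean of at least 10 TPM in the other are given as counts with at most 5 examples. Other genes are named only where the text says so. Since genes that every cell uses are at 0 in F. intonsa, a 0 is called a listing, F. intonsa values are given per library, and no fold is given for a gene against a group listed at 0. The median over all genes of the species comparison and its list tests still include the fitted values of such genes.

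The tests were checked on simulated data with 200 changed genes. These used the means of F. occidentalis females and, for each gene, 1 spread for both groups, with independent normal noise. Version 1 drew noise from each gene's residual spread with log2 changes of 1 and 2, and recovered 0% and 0% in the sex comparison (22015 genes) and 12% and 49% in the species comparison (21231 genes). Version 2 drew noise from the fitted prior and recovered 0% and 1% (sex) and 0% and 28% (species). Version 3 added a change of 4 and took changed genes from a mean log2 above 5, and recovered 1.67%, 60% and 98.8% (sex) and 0%, 1.67% and 25% (species). Version 4, which is the one reported, kept the change of 4 and returned to a mean log2 above 2, and recovered 0%, 25% and 80% for changes of 1, 2 and 4 (sex) and 0%, 28.3% and 65% (species). All changed genes called had the right sign. Among calls, 6 of 85 (sex) and 10 of 79 (species) were unchanged genes. Of unchanged genes, 5.15% (sex) and 4.92% (species) had an unadjusted p under 0.05 (limma-trend). The noise of version 4 follows the spread that the test assumes, so a share near 5% was built in and does not check the real data. Genes listed at 0 in only 1 species and unequal spreads of the groups were not simulated. The species values therefore do not describe the real species comparison. Recovery of small changes was low in these simulations at 3 libraries per group.

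The alternatives planned before the data were examined were quantile normalization, limma without trend, no filter, a stricter filter (5 TPM), a pseudocount of 0.1, a log2 fold of at least 1, all 9 libraries in 1 fit, the replicate number as a block, summing of genes with the same annotation, an estimated correlation, the tested genes as denominator of the shares, and leaving out each library. Added after the data were seen were summing of assembly components, genes above 0 in both species, leaving out microsporidian matches, F. intonsa library 2 alone, and lists limited to genes with the family's domain. Results were also computed for the 10 splits of each comparison's 6 libraries into 3 and 3.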

Results

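Gene expression was measured by RNA sequencing in antennae of 1 day old adult thrips. The 9 libraries fell into 3 groups of 3: female Frankliniella occidentalis (the western flower thrips), male F. occidentalis and female Frankliniella intonsa. Male F. intonsa were not analysed here. The table held 48889 assembled genes with values in TPM (a length-scaled share of a library's transcripts), in 1 assembly shared by both species, and 21362 of them (43.7%) had a database match. The TPM of a library summed to between 935518 and 987791. TPM keeps no record of the number of reads, so the depth of each library is unknown and no interval or detection floor is given. The labels do not say whether replicates came from separate insects or pools, so the p-values measure the spread between these samples, which may be technical.

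The series title asks how odorant-binding proteins (OBPs) and chemosensory proteins (CSPs) compare between the species. Both are families of small soluble proteins, and OBPs carry odorants through the fluid of insect sensilla. Of the 48889 genes, 9928 were above 0 in both species, 18034 in F. occidentalis alone and 20927 in F. intonsa alone. Genes above 0 in both species held 56.6% ± 0.592 (SD, n = 3) of TPM in F. occidentalis females and 57.9% ± 1.32 (SD, n = 3) in males. In F. intonsa they held 19.9%, 30.4% and 21.5% in libraries 1, 2 and 3.

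The F. intonsa libraries differed from each other more than the F. occidentalis libraries did. Genes without a database match took 24.8% ± 1.43 of TPM in F. occidentalis females and 27.8% ± 1.97 in males (SD, n = 3 each). In F. intonsa they took 85.1%, 44.4% and 92.4% in libraries 1, 2 and 3. Genes whose annotation text names WN48_00612 count as matched. They held 24.8% to 32.4% of TPM in the F. occidentalis libraries, and 0.00237%, 1.61% and 0.000598% in F. intonsa libraries 1, 2 and 3. The number of genes above 0 was 16360, 28515 and 10556 in these libraries, against 22666 to 24204 in the 6 F. occidentalis libraries. Spearman correlations across genes, which are not independent replicates, were 0.897 to 0.914 between F. occidentalis females, 0.789 to 0.857 between males and 0.296 to 0.571 between F. intonsa libraries. At most 0.444% of nonzero values were identical between any pair of libraries.

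**Figure D1:**
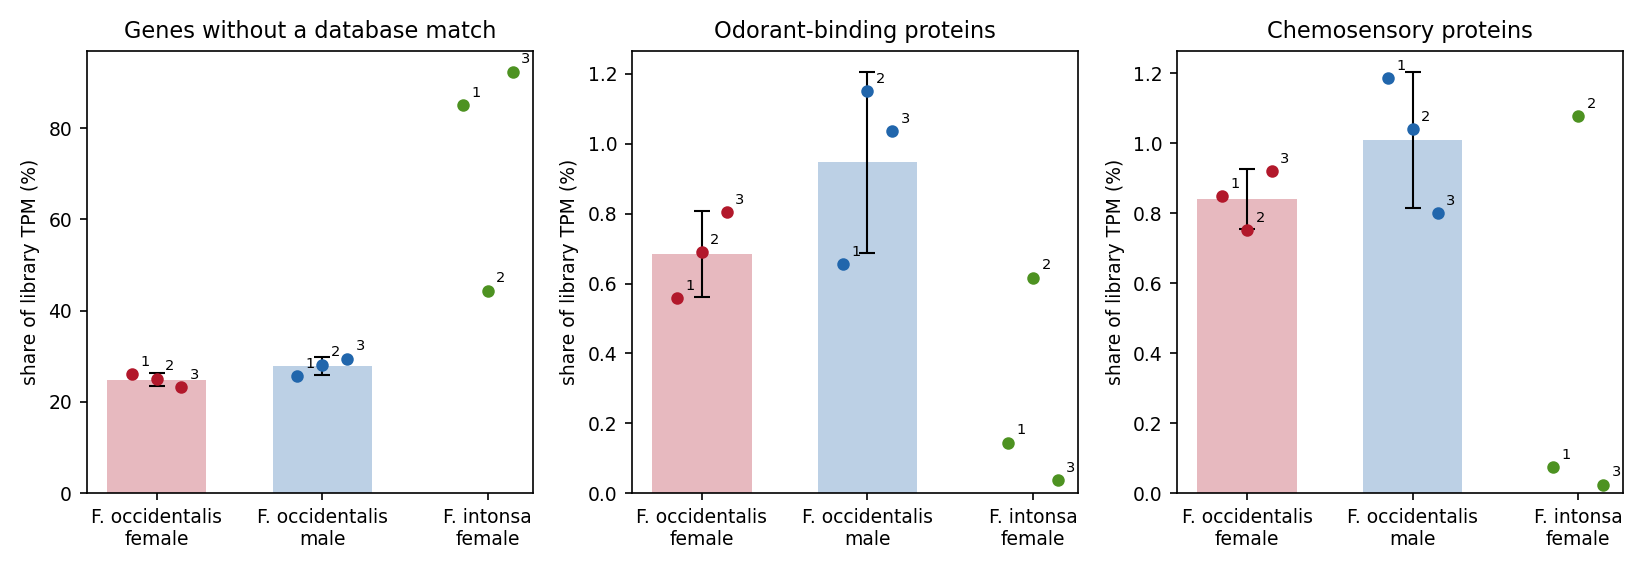
Share of each library's TPM (percent, y axis) in genes without a database match, in OBPs and in CSPs, by group. Points are libraries with their replicate numbers. Bars and whiskers are the mean ± SD of 3 libraries, drawn for F. occidentalis alone. In F. intonsa the unmatched share was 85.1%, 44.4% and 92.4% in libraries 1, 2 and 3, and library 2 had the highest OBP and CSP shares of its group.

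Male and female F. occidentalis antennal libraries differed most in transcripts of yolk protein precursors. These transcripts belong to the fat body list, which was fixed as a marker list of another tissue. Whether they came from the antennae or from other tissue carried with them was not tested. Vitellogenin, the main yolk protein precursor of insects, had a log2 fold change of −9.24 ± 0.36 (SE, n = 3 per sex) of TPM + 1 in males at TRINITY_DN44590_c1_g3, from 3075 ± 1173 TPM to 3.88 ± 1.11 TPM (SD; adjusted p = 3.65e-06, limma-trend). Another 3 assembled genes annotated as vitellogenin had log2 fold changes of −8.63, −8.42 and −8.25. The genes at −9.24 and −8.63 had listed lengths of 274 and 1170, and the former was annotated as partial. Whether these genes are parts of the same transcript was not tested, so they need not be independent. A gene matching FMRFamide-related neuropeptides (TRINITY_DN38821_c0_g2), with no protein domain annotated, was at 152 ± 43.5 TPM in females and rose to 862 ± 241 TPM in males (SD, n = 3 each). Its log2 fold change was 2.50 ± 0.32 (SE; adjusted p = 0.00894, limma-trend), a call lost without female library 1 or 2. A gene matching takeout, a protein of the juvenile hormone binding family (TRINITY_DN35733_c0_g3), rose from 2.18 ± 1.71 to 74.1 ± 21.6 TPM (SD, n = 3 each), a log2 fold change of 4.66 ± 0.44 (SE; adjusted p = 0.000944).

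Of 22015 genes tested with limma-trend, 415 passed an adjusted p of 0.05, 213 higher and 202 lower in males, and 3415 had an unadjusted p under 0.05. All 415 had sexes whose 3 libraries did not overlap. Of all tested genes, 20.1% did not overlap, against 10% by chance. The median log2 fold change of all tested genes was 0.19, and −0.02 after quantile normalization. With that normalization 207 genes passed, 65 higher and 142 lower, so the split between directions depends on the scaling. It also moved the other way, to 582 higher and 191 lower among genes above 0 in both species and to 190 and 95 without male library 2. Leaving out 1 library left 18, 23 and 36 genes without female libraries 1, 2 and 3, and 153, 285 and 183 without male libraries 1, 2 and 3. Other counts were 198 with limma without trend, 116 without a filter on low values, and 271 with a pseudocount of 0.1.

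The genes named by the fixed rule for the largest changes fell into several functions. Among those higher in males were a very long chain fatty acid elongase (TRINITY_DN45545_c0_g4, log2 fold change 3.27 ± 0.34 SE), phenylalanine-tryptophan hydroxylase (2.88), a superoxide dismutase (2.77), a thioredoxin reductase (2.73), the large subunit of ribonucleotide reductase (2.54) and a cdc20-like cell cycle protein (2.46). The ribosomal proteins S29, L29 and L37 were higher by 2.70, 2.44 and 2.38, and the L37 gene's Swiss-Prot match was a microsporidian. The superoxide dismutase, thioredoxin reductase, cdc20-like and FMRFamide-related genes had a butterfly, Papilio xuthus, as their matched organism, as did 41 of all 213 genes higher in males, and the Swiss-Prot matches of the first pair were a green alga and rice. Among those lower in males were inositol monophosphatase 2 (TRINITY_DN42396_c0_g1), with a log2 fold change of −3.84 ± 0.67 (SE), a decarboxylase of the uric acid pathway (TRINITY_DN43505_c0_g3, −3.51), and the ribosomal proteins L13a (−3.06) and L36 (−2.83). Diazepam binding inhibitor, which binds acyl-CoA, was at −2.57, sorbitol dehydrogenase at −2.41, phytanoyl-CoA dioxygenase at −2.25 and inositol oxygenase at −2.23. The 20 genes with the largest changes had adjusted p-values (limma-trend) from 3.65e-06 to 0.0465. Of all 31 genes named by the rule and past the threshold, 6 stayed past it with quantile normalization, the replicate block, all 9 libraries in 1 fit and each library left out, wherever they could be tested: the 4 vitellogenins, the takeout-like gene and cytochrome P450 4AB8 (TRINITY_DN45510_c0_g3). The 4 vitellogenins may be parts of the same transcript, so they need not count as 4 separate genes. Among the 31, leaving out 1 library ended the call of 22, and quantile normalization that of 10.

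**Figure D2:**
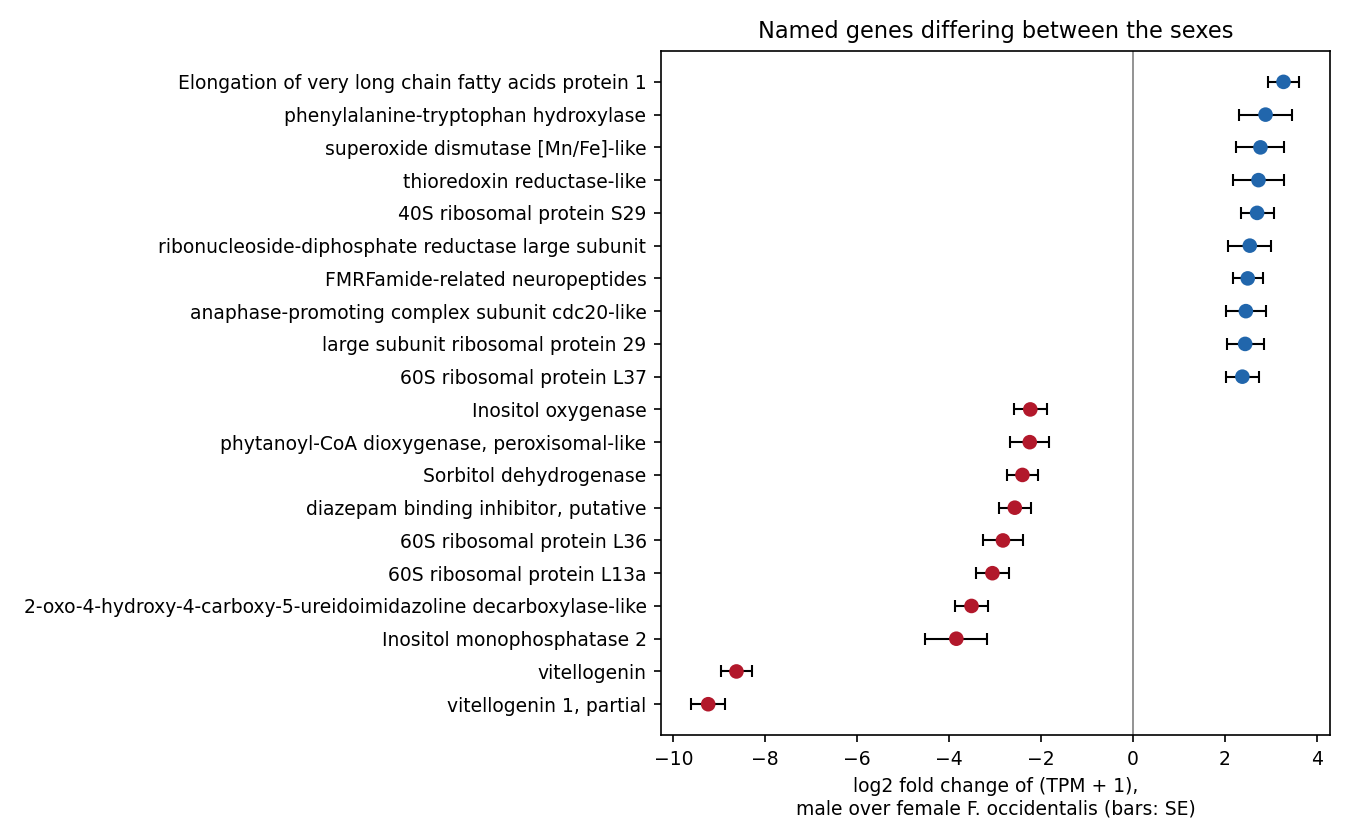
Log2 fold change of TPM + 1 (x axis), males over females of F. occidentalis, for the 10 named genes with the largest rise (blue) and the 10 with the largest fall (red) past an adjusted p of 0.05. Points are fitted values from 3 libraries per sex and bars are standard errors. The vitellogenin genes lie at −9.24 and −8.63, and the other falls between −3.84 and −2.23.

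Gene groups fixed before the data were examined are given with their median log2 fold change relative to that of all tested genes. Members of a list are assembled genes, and some may be parts of the same transcript. Counts of members and list tests therefore need not rest on separate genes. Fat body genes, which include the vitellogenins, had 35 of 49 tested members lower in males and 0 higher (38 lower, adjusted over the list alone), with a relative median of −6.52 (camera adjusted p = 1.32e-84; adjusted p = 0.118 with an estimated correlation). Ribosomal protein genes had 65 of 270 lower and 28 higher (125 and 83, adjusted over the list alone), with a relative median of −0.87 (adjusted p = 6.5e-07; adjusted p = 0.702 with an estimated correlation). Within that list, medians are given as fitted and not relative to all genes (−0.69 for the whole list). The 29 members whose Swiss-Prot match was a microsporidian had a median of 1.76, with 10 higher and 0 lower. The other 241 had a median of −1.01, with 18 higher and 65 lower. Oxidative phosphorylation genes had 0 of 111 members past the threshold, also adjusted over the list alone, and a relative median of −0.69 (adjusted p = 9.57e-17; adjusted p = 0.454 with an estimated correlation). None of the 11 lists that camera called in the sex comparison with the preset correlation of 0.01 was called with an estimated correlation, where their adjusted p-values ran from 0.118 to 0.738.

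In the groups linked to turnover of odorants and xenobiotics, few genes passed the threshold. Among 131 cytochromes P450, 3 were lower in males and 0 higher (4 and 2, adjusted over the list alone). They were P450 4AB8, with a log2 fold change of −3.08 ± 0.48 (SE), and TRINITY_DN45077_c3_g11 (−1.86) and TRINITY_DN45264_c0_g5 (−1.44). The calls of these last genes were lost with quantile normalization, with the replicate number as a block, and without any library other than male 3. Among 54 carboxylesterases, 1 was lower and 0 higher (3 and 0, adjusted over the list alone). This venom carboxylesterase-6-like gene (TRINITY_DN44505_c0_g2) fell from 16.3 ± 4.98 TPM in females to 0.05 ± 0.0866 TPM in males (SD, n = 3 each; limma-trend adjusted p = 0.00184). Among 37 glutathione S-transferases, 1 was lower and 0 higher (4 and 0, adjusted over the list alone). It was sigma 1 (TRINITY_DN44613_c0_g6), which had a log2 fold change of −2.14 ± 0.25 (SE; adjusted p = 0.00465), a call lost without female library 1 or 2. That list had a relative median of −0.39 (camera adjusted p = 0.0182; adjusted p = 0.299 with an estimated correlation). UDP-glycosyltransferases had 0 of 32 past the threshold and a relative median of −0.49 (adjusted p = 0.000926; adjusted p = 0.702 with an estimated correlation). ABC transporters had 0 of 80 and a relative median of 0.20 (adjusted p = 0.0229; adjusted p = 0.702 with an estimated correlation). Quantile normalization ended the calls of glutathione S-transferases (adjusted p = 0.455) and ABC transporters (0.0631), as did leaving out male library 1 for the former (0.0573) and female library 1 (0.129) or male library 3 (0.226) for the latter. Of 29 takeout and juvenile hormone binding genes, 1 was higher and 2 lower (2 and 3, adjusted over the list alone).

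Markers of other tissues were included because antennal samples can carry them. Fat body genes, given above, are such a list and had the largest shift, from 1.04% ± 0.310 of TPM in females to 0.0155% ± 0.00420 in males (SD, n = 3 each). Cuticle proteins, also given here, were fixed as a group of their own. Muscle genes (0 of 62 past the threshold) had a relative median of −0.41 (camera adjusted p = 0.000436; adjusted p = 0.702 with an estimated correlation). Gut and salivary gland genes (0 of 74) had a relative median of −0.43 (adjusted p = 0.00398; adjusted p = 0.268 with an estimated correlation). Eye genes (0 of 32) had a relative median of −0.63 (adjusted p = 0.0293; adjusted p = 0.738 with an estimated correlation), and cuticle proteins (0 of 77) one of −0.22 (adjusted p = 0.00776; adjusted p = 0.196 with an estimated correlation). Without male library 2 the calls of eye genes (adjusted p = 0.900), gut genes (0.0796), cuticle proteins (0.0626), glutathione S-transferases (0.0730) and ABC transporters (0.0673) were lost, and quantile normalization ended those of eye (0.155) and muscle genes (0.0898). All 9 libraries in 1 fit also ended the eye and muscle calls (0.0910 each), summing by annotation those of eye genes (0.131) and glutathione S-transferases (0.215), and summing components those of eye genes (0.162), gut genes (0.176), cuticle proteins (0.0813), glutathione S-transferases and ABC transporters (0.610 each). The 15 lists not called had adjusted p-values from 0.0646 to 0.971. They were OBPs, CSPs, the odorant, ionotropic and gustatory receptors, cytochromes P450, carboxylesterases, takeout and juvenile hormone binding genes, heat shock proteins, neuronal, axonemal and sperm, ovary, immune and sex determination genes, and microbial and viral matches.

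Neither chemosensory family named in the title had a member past the threshold between the sexes. OBPs held 0.684% ± 0.124 of TPM in females and 0.947% ± 0.259 in males (SD, n = 3 each; exact two-sided permutation p = 0.3, where 0.1 is the smallest that 3 against 3 allow). CSPs held 0.840% ± 0.0847 in females and 1.01% ± 0.195 in males (SD, n = 3 each; exact two-sided permutation p = 0.3). Of 16 OBP and 15 CSP genes tested with limma-trend, 0 passed the threshold. Adjusted over the list alone, 0 OBP genes and 1 gene of the CSP list passed. That gene (TRINITY_DN38554_c0_g3), named after its values were seen, matched sensory neuron membrane protein 2 in Swiss-Prot and was at 26.6 ± 9.43 TPM in females and 77.9 ± 26.8 TPM in males (SD, n = 3 each). The OBP list leaned towards males (relative median 0.22; camera adjusted p = 0.155; adjusted p = 0.746 with an estimated correlation). It passed the threshold after quantile normalization (adjusted p = 0.0208) and without male library 1 (adjusted p = 0.00277). The CSP list leaned towards females (relative median −0.20; adjusted p = 0.549; adjusted p = 0.746 with an estimated correlation), and towards males after quantile normalization (adjusted p = 0.690). The 5 genes of highest mean in each list had log2 fold changes from −0.02 to 0.63, and the OBP and CSP genes of highest mean were at 1778 ± 372 TPM (TRINITY_DN37663_c0_g1) and 2991 ± 315 TPM (TRINITY_DN43094_c3_g1) in females (SD, n = 3).

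Odorant receptors held 0.00413% ± 0.000930 of TPM in females and 0.00505% ± 0.00193 in males (SD, n = 3 each; exact two-sided permutation p = 0.6). None of 9 odorant receptors, 4 ionotropic receptors and 9 gustatory receptors passed the threshold between the sexes, over all genes or adjusted over the list alone. Sensory neuron membrane proteins, which lie in the membrane of olfactory neurons and their support cells, had 0 of 6 past the threshold (3 higher in males, adjusted over the list alone) and a relative median of 0.98 (camera adjusted p = 0.0361; adjusted p = 0.702 with an estimated correlation). The call was lost without female library 1 (adjusted p = 0.105), male library 2 (0.0964) or male library 3 (0.182), and with all 9 libraries in 1 fit (0.339), genes of the same annotation summed (0.106) or components summed (0.0813). Their summed share of TPM was 0.00603% ± 0.00198 in females and 0.0159% ± 0.00559 in males (SD, n = 3 each; exact two-sided permutation p = 0.1, the smallest possible). The 3 genes higher in males, adjusted over the list alone, were looked up after their values were seen. They include TRINITY_DN38554_c0_g3, the gene of the CSP list above. The others belong to the same assembly component, TRINITY_DN43453_c0.

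Between the females of the species, most genes past the threshold were listed at 0 in all libraries of one of them. Of 21231 genes tested with limma-trend, 18127 passed the threshold, 3625 higher and 14502 lower in F. intonsa, and 18257 had an unadjusted p under 0.05. In 14835 of the 18127, one species was listed at 0 in all its libraries, and no fold is given for these. They include genes that every cell uses: cytochrome c oxidase subunits I, III, 5A and 6A were listed at 0 in all 3 F. intonsa libraries on the genes that held 2582 ± 525, 3917 ± 442, 2497 ± 64.9 and 5588 ± 328 TPM in F. occidentalis females (SD, n = 3). A value of 0 is therefore only a listing and says nothing of whether the gene is expressed. Groups did not overlap in 86.6% of tested genes. A gene listed at 0 in one species was tested only with at least 1 TPM in all 3 libraries of the other. Its groups therefore cannot overlap, and this share has no chance rate to be set against.

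The median log2 fold change of all genes tested between the species was −2.35, and −0.20 after quantile normalization, with which 11047 genes passed, 4538 higher and 6509 lower. This median includes fitted values of genes listed at 0 in one species, which depend on the pseudocount (−5.18 with 0.1), so it measures no fold between the species, and no median of a list is given. The list tests rest on the same fitted values. When all genes of one assembly component were summed first, 6081 components passed, 1847 higher and 4234 lower. Among genes above 0 in both species 3128 passed, 569 higher and 2559 lower. With F. intonsa library 2 alone, where libraries 1 and 3 were left out because of their unmatched share, 15098 genes passed. That fit assumes that the lone library varies like the others. Leaving out F. occidentalis libraries 1, 2 and 3 left 3612, 3472 and 3346 genes with most of them higher in F. intonsa (2868, 2809 and 2718), because genes listed in F. occidentalis alone could then not reach the minimum in 3 libraries. Leaving out F. intonsa libraries 1, 2 and 3 left 14252, 16126 and 14619, of which 183, 333 and 497 were higher in F. intonsa, against 3625 with all libraries. Genes listed in F. intonsa alone could then not reach that minimum, and the same holds with F. intonsa library 2 alone.

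Among genes above 0 in both species, the named genes with the largest rises in F. intonsa had means of 1.28 to 4.10 TPM in F. occidentalis females. They include a mitochondrial cytochrome b gene at 1.99 TPM, where the cytochrome c oxidase subunits I and III held 2582 and 3917 TPM. Such low values, like a 0, list 1 assembled gene and do not measure how much a species expresses that function, so the fold changes below hold for assembled genes alone. A cold shock domain-containing protein E1 gene (TRINITY_DN45925_c0_g2) was at 1160, 268 and 427 TPM in F. intonsa libraries 1, 2 and 3 and at 1.96 ± 0.223 TPM in F. occidentalis (SD, n = 3), a log2 fold change of 7.44 ± 0.62 (SE). The cytochrome b gene was at 6.15, ribosomal proteins L44, L12 and L23 at 5.97, 5.25 and 5.14, and the iron-sulfur cluster assembly 1 homolog at 4.85. The calls of an ATP synthase lipid-binding protein (5.72), HEAT repeat-containing protein 5B (5.18) and a VAT-1 homolog (4.97) were each lost when any 1 of the 3 F. occidentalis libraries was left out. Lower in F. intonsa was a small heat shock protein (TRINITY_DN42286_c0_g3), with a log2 fold change of −9.66 ± 0.94 (SE), from 1666 ± 275 TPM in F. occidentalis (SD, n = 3) to 0, 7.25 and 0.04 TPM in the F. intonsa libraries. A troponin I gene was at −7.96, and 4 genes annotated as vitellogenin or vitellogenin-like at −7.97, −7.77, −7.52 and −7.35. A thioredoxin-like gene was at −7.58, another small heat shock protein at −7.29 and a gene matching troponin C at −7.50, and the calls of these last 2 were lost without F. intonsa library 1 or 3, and that of the latter also without F. occidentalis library 1 or 3. The 20 genes with the largest changes between the species had adjusted p-values (limma-trend) from 3.18e-05 to 0.0416.

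OBP and CSP genes were also divided between the species. Of 27 OBP genes in the table, 13 were above 0 in F. occidentalis alone, 10 in F. intonsa alone and 4 in both. Of 21 CSP genes, 6, 6 and 9 were so divided, and of all 48889 genes 18034, 20927 and 9928. Whether these proportions differ was not tested. A conserved domain of its family was annotated in 17 OBP and 17 CSP genes. Among 20 OBP genes tested, 14 were lower and 4 higher in F. intonsa (15 and 4, adjusted over the list alone). Among 18 CSP genes, 9 were lower and 3 higher, also adjusted over the list alone. All 4 OBP and 3 CSP genes higher in F. intonsa were listed at 0 in F. occidentalis females. Most of the lower genes of both lists were listed at 0 in F. intonsa, so most of these calls are listings. Of all 21231 genes tested, 14502 were lower and 3625 higher. The OBP gene of highest mean, TRINITY_DN37663_c0_g1, was at 0, 22.3 and 0 TPM in F. intonsa libraries 1, 2 and 3. The next, TRINITY_DN41677_c1_g5 (1380 ± 351 TPM), TRINITY_DN44889_c0_g1 (1268 ± 172 TPM) and TRINITY_DN42607_c0_g1 (934 ± 212 TPM, SD, n = 3 each in F. occidentalis females), were listed at 0 in all F. intonsa libraries. Conversely, OBP genes TRINITY_DN41677_c1_g3 (317, 1554 and 160 TPM in F. intonsa libraries 1, 2 and 3) and TRINITY_DN44060_c0_g8 (316, 1599 and 143.5 TPM) were listed at 0 in F. occidentalis. The CSP gene TRINITY_DN39605_c1_g3 was measured in both, at 1023 ± 286 TPM in F. occidentalis females (SD, n = 3) and at 148, 4964 and 63.5 TPM in F. intonsa (log2 fold change −1.46 ± 1.78 SE, adjusted p = 0.474).

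Summing all genes of an assembly component, an alternative chosen after the data were seen, also adds genes outside the OBP and CSP lists. Of 11 OBP components tested, 1 was higher and 6 lower in F. intonsa. Of 10 CSP components, 0 were higher and 2 lower. No component of either family passed the threshold between the sexes. The components below were named after their values were seen. The higher OBP component, TRINITY_DN44060_c0, was at 316, 1610 and 143.5 TPM in F. intonsa libraries 1, 2 and 3 and 4.69 ± 3.25 TPM in F. occidentalis females (SD, n = 3), a log2 fold change of 6.44 ± 1.15 (SE; adjusted p = 0.00476). Its F. occidentalis value came from genes outside the OBP list, since both of its OBP genes were listed at 0 there. In the lower component TRINITY_DN44933_c0, 2 OBP genes held 3.36 and 3.25 TPM of 93.7 TPM in F. occidentalis females. Of the other lower OBP components, TRINITY_DN37663_c0 held 1790 ± 377 TPM in F. occidentalis and 0.07, 47.7 and 0 TPM in F. intonsa, and TRINITY_DN42607_c0 held 1205 ± 211 TPM in F. occidentalis and was listed at 0 in F. intonsa. The component TRINITY_DN41677_c1 held 1434 ± 372 TPM in F. occidentalis and 348, 1807 and 160 TPM in F. intonsa, and did not pass the threshold (adjusted p = 0.220). Among CSPs, TRINITY_DN43094_c3 held 4906 ± 624 TPM in F. occidentalis and 4.17, 649 and 2.56 TPM in F. intonsa, a log2 fold change of −7.74 ± 2.09 (SE; adjusted p = 0.0235). The other lower component, TRINITY_DN13342_c0, held 30.1 ± 11.3 TPM in F. occidentalis and was listed at 0 in F. intonsa.

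**Figure D3:**
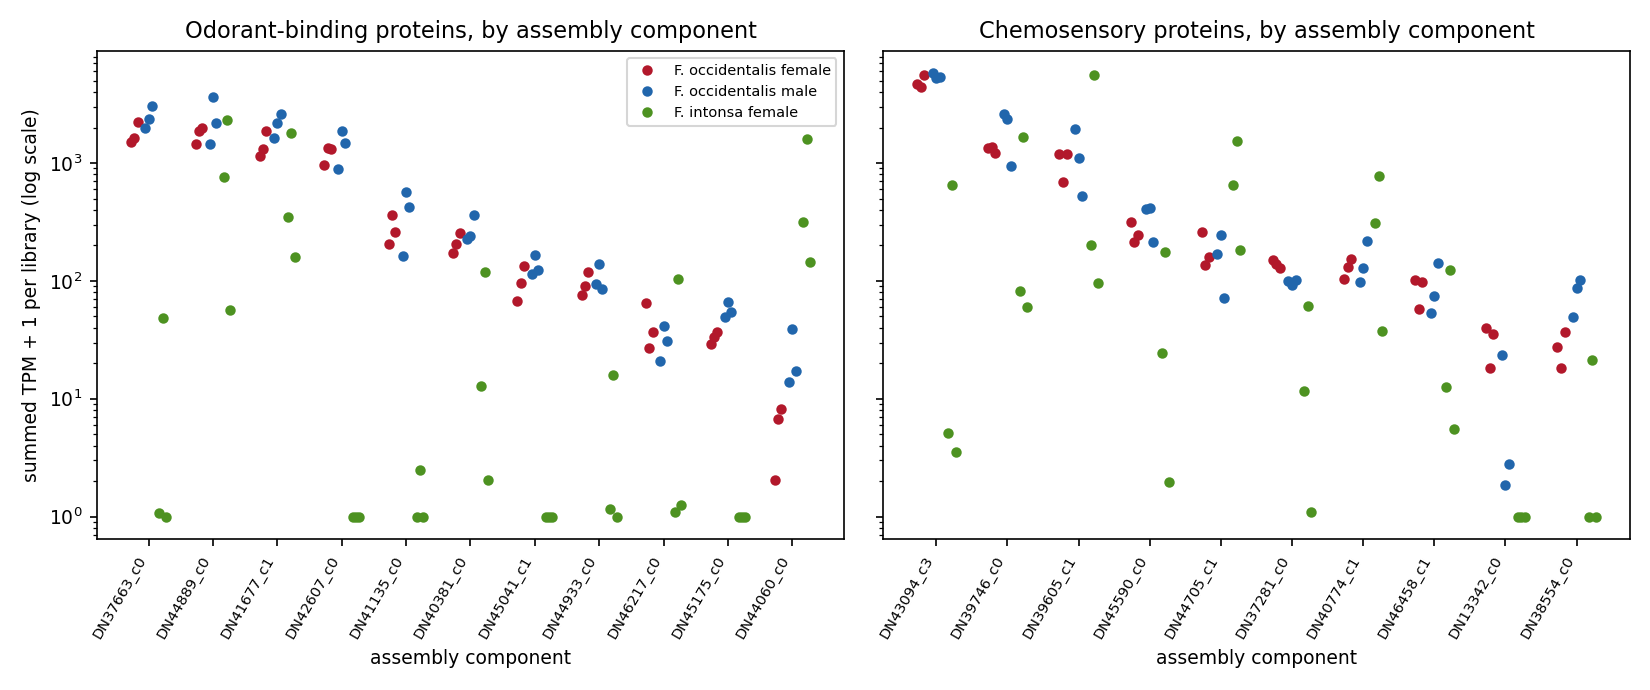
Summed TPM + 1 (y axis, log scale) of each tested OBP (left) and CSP (right) assembly component (x axis), with 1 point per library and colour by group. Components are ordered by their mean in F. occidentalis females. The F. intonsa points spread widely within a component, and TRINITY_DN44060_c0 is the OBP component past the threshold with higher values in F. intonsa (316, 1610 and 143.5 TPM). Sums include genes outside the lists.

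The summed shares of both families did not separate the species. OBPs held 0.145%, 0.617% and 0.0365% of TPM in F. intonsa libraries 1, 2 and 3, against 0.684% ± 0.124 in F. occidentalis females (SD, n = 3; exact two-sided permutation p = 0.2). CSPs held 0.0741%, 1.08% and 0.0244%, against 0.840% ± 0.0847 (SD, n = 3; exact two-sided permutation p = 0.4). These are shares of all TPM. Unmatched genes (85.1%, 44.4% and 92.4% in F. intonsa libraries 1, 2 and 3) therefore leave less for matched genes as a whole. That need not hold for each list. WN48_00612 genes count as matched and held 26.4% ± 1.51 in F. occidentalis females (SD, n = 3), but 1.61% in F. intonsa library 2. ABC transporters held 0.202%, 0.262% and 0.247% in F. intonsa libraries 1, 2 and 3, against 0.0981% ± 0.00578 in F. occidentalis females (SD, n = 3). As lists, OBPs had a direction of lower (camera adjusted p = 0.773; adjusted p = 0.966 with an estimated correlation). CSPs had a direction of higher in the test, though their median lay below that of all genes (adjusted p = 0.720; adjusted p = 0.966 with an estimated correlation). After quantile normalization the CSP direction was lower (adjusted p = 0.349). With F. intonsa library 2 alone, OBPs were called lower and CSPs higher (adjusted p = 0.0440 each), and without that library OBPs were called lower (adjusted p = 0.0377). In both, 16 of the 20 OBP genes and 15 of the 18 CSP genes were left, because those listed in F. intonsa alone, among them all 4 OBP genes higher in F. intonsa, could not reach the minimum in 3 libraries. These calls therefore say nothing of the direction of the whole OBP list.

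Among the other lists in the species comparison, 3 of 26 were called with the preset correlation and 0 with an estimated one. Cytochromes P450 had 112 of 132 members lower and 7 higher in F. intonsa, the same counts adjusted over the list alone (camera adjusted p = 0.00441; adjusted p = 0.966 with an estimated correlation). That call was lost when any 1 of the 3 F. occidentalis libraries was left out (adjusted p = 0.141 to 0.249) and when components were summed (0.0638). The cytochrome P450 share of TPM was 0.0351%, 0.504% and 0.0147% in F. intonsa libraries 1, 2 and 3, so it was lowest in libraries 1 and 3. In F. occidentalis females it was 0.833% to 1.07%. Ribosomal proteins had 85 of 316 higher and 118 lower (81 and 108, adjusted over the list alone) and a direction of higher (adjusted p = 0.000147; adjusted p = 0.966 with an estimated correlation), which turned to lower without each F. occidentalis library (adjusted p up to 0.318). Quantile normalization ended both the ribosomal call (adjusted p = 0.285) and that of oxidative phosphorylation (0.881), as did no filter (0.555 and 0.428), and summing components ended the ribosomal call (0.388). Oxidative phosphorylation genes had 88 of 194 higher and 95 lower, the same counts adjusted over the list alone. Their median lay below that of all genes although the test's direction was higher (adjusted p = 4.88e-05; adjusted p = 0.966 with an estimated correlation), and the direction was lower without each F. intonsa library and with library 2 alone (adjusted p = 2.85e-08). The minimum in 3 libraries also removes genes of one species in these left-out fits. The other 23 lists had adjusted p-values from 0.0580 to 0.943. After quantile normalization 7 of them were called lower in F. intonsa: fat body genes (adjusted p = 0.000190), UDP-glycosyltransferases (0.00689), glutathione S-transferases (0.00791), takeout and juvenile hormone binding genes (0.00791), eye genes (0.0148), immune genes (0.0282) and carboxylesterases (0.0340). These 7 calls used the preset correlation. With an estimated correlation and no quantile normalization, each of these lists had a camera adjusted p of 0.966. Past the threshold on the lower side in F. intonsa were 6 odorant receptors of 9 tested, 2 ionotropic receptors of 3 and 3 gustatory receptors of 6. Both of these ionotropic receptors and 2 of these gustatory receptors were listed at 0 in all F. intonsa libraries, which says nothing of whether they are expressed, and after quantile normalization the direction of each of these 3 lists was higher. Of 11 odorant receptors in the table, 1, 5 and 0 reached 1 TPM in F. intonsa libraries 1, 2 and 3. The odorant receptor calls therefore also rest on values at or near 0 in libraries 1 and 3.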

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

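Quantile normalization, limma without trend, no filter, a stricter filter, a pseudocount of 0.1, a single fit of all 9 libraries, the replicate block, summing by annotation and leaving out libraries were planned. Summing assembly components, genes above 0 in both species, F. intonsa library 2 alone and lists limited to the family domain were chosen after the data were seen. Planned count tests and a comparison with another unit were not run, since the table holds TPM alone, so the effect of depth was not measured. When a library is left out of the species comparison, or F. intonsa library 2 is used alone, the minimum in 3 libraries removes genes listed only in the species with fewer than 3 libraries. For the other changes below, the cause was not tested.

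The number of genes differing between the sexes (415) was 207 with quantile normalization, 198 with limma without trend, 116 with no filter, 271 with a pseudocount of 0.1, 773 among genes above 0 in both species, and 18 to 285 when 1 library was left out. Of the 415, 204 were shared with quantile normalization and 151 with limma without trend. The number differing between the species (18127) was 11047 with quantile normalization, 9243 with a stricter filter, 6081 with assembly components summed, 3128 among genes above 0 in both species, 6139 with F. intonsa library 2 alone and components summed, and 3346 to 16126 when 1 library was left out. With the replicate number as a replicate block, 363 genes differed between the sexes and 18104 between the species. The numbers do not pair the libraries: residual correlations across genes between libraries of different groups ran from −0.04 to 0.06 between the sexes and from −0.06 to 0.06 between the species, for equal and unequal numbers.

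For the OBP list in the sex comparison the adjusted p was 0.0208 with quantile normalization and 0.00277 to 0.661 when 1 library was left out, within 0.00277 to 0.746 over all alternatives. For the CSP list in the sex comparison it was 0.690 with quantile normalization, where the direction turned, and 0.206 to 0.715 when 1 library was left out (0.177 to 0.746 over all). For the OBP list in the species comparison the direction turned with genes of the same annotation summed (0.981) and with the family domain required (0.857). The adjusted p was 0.0440 with F. intonsa library 2 alone and 0.0377 to 0.756 when 1 library was left out (0.0377 to 0.981 over all). For the CSP list in the species comparison the direction turned with quantile normalization (0.349), no filter (0.455) and components summed (0.818). The adjusted p was 0.0440 with F. intonsa library 2 alone and 0.0964 to 0.917 when 1 library was left out (0.0440 to 0.981 over all). The ribosomal list in the species comparison ran from 2.05e-07 to 0.318 when 1 library was left out. The oxidative phosphorylation list turned with F. intonsa library 2 alone (2.85e-08), with components summed as well (0.583), and ran from 1.69e-08 to 9.79e-06 when 1 library was left out.

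The difference in OBP share kept its direction in 7 of 7 alternatives (0.162 to 0.409 percentage points between the sexes, −0.593 to −0.303 between the species), as did that in CSP share (0.0804 to 0.273 and −0.791 to −0.264). None of these alternatives takes out the unmatched genes, whose large share in F. intonsa leaves less TPM for matched genes as a whole. The kept direction between the species therefore does not separate the families from that share. Among named genes, direction turned between the sexes when 1 library was left out for TRINITY_DN44889_c0_g1 (log2 fold change −0.056 to 0.56), TRINITY_DN42607_c0_g1 (−0.11 to 0.41), TRINITY_DN43094_c3_g1 (−0.16 to 0.13, and 0.29 with quantile normalization) and TRINITY_DN39605_c1_g3 (−0.38 to 0.56), none of which was called. Between the species it turned with quantile normalization for TRINITY_DN43885_c0_g4 (0.11), TRINITY_DN38529_c0_g1 (0.21) and TRINITY_DN42827_c0_g1 (0.96). Of 31 named genes called between the sexes, 22 lost the call when 1 library was left out, 11 with all 9 libraries in a single fit, 10 with quantile normalization and 3 with the replicate block. Of 124 called between the species, 10 lost it when 1 library was left out, 8 with quantile normalization besides the 3 that turned, and 1 with the replicate block. Many of the 124 could not be tested without a library of the only species that lists them. The 10 therefore rests on 468 left-out values, against 177 for the 31 genes between the sexes. Of the lists called between the sexes, sensory neuron membrane proteins lost the call in 7 alternatives and kept it in 6. Glutathione S-transferases, ABC transporters and eye genes lost it in 6 and kept it in 7, cuticle, muscle and gut genes lost it in 3, and the other 4 lost it in 1, the estimated correlation.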

Other observations

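All tests below except that of genes that the other species lacks were chosen only after the result was seen. Genes at 0 in all 3 libraries of one group with a mean of at least 10 TPM in the other were counted in both comparisons. Of 33 such genes listed at 0 in males, 7 had a named product, among them 3 vitellogenin genes with female means of 82.2, 21.9 and 15.4 TPM, and of 15 listed at 0 in females, 2 had one. Between the species, 4560 genes were listed at 0 in F. intonsa and 4614 in F. occidentalis females. The latter include ATP synthase subunit e (2439, 4498 and 440.4 TPM in F. intonsa libraries 1, 2 and 3) and a defensin, an antimicrobial peptide (59.2, 6497 and 2.04 TPM).

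Genes whose database match was a bacterium held 0.415% to 0.836% of TPM in the F. occidentalis libraries and 0.184%, 0.242% and 0.331% in F. intonsa libraries 1, 2 and 3. Plant matches held 0.392% to 0.506% and 0.258%, 0.315% and 0.0556%. Pig matches held 0.253%, 0.272% and 0.319% in F. intonsa and at most 0.00201% in F. occidentalis. Microsporidian matches (145 genes) held 0.0776%, 0.0693% and 0.0919% in females 1, 2 and 3, 0.373%, 0.178% and 0.404% in males, and 0.113%, 0.0416% and 0.00803% in F. intonsa.

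F. intonsa libraries 1 and 3 stood apart from library 2 in their unmatched share. Shallower sequencing would leave log2 ratios to library 2 near 0 in genes chosen by a library that is not compared, yet the median was 4.47 in library 1 over 739 genes of at least 100 TPM in library 3 (quartiles 2.64 and 5.50), and 3.02 in library 3 over 1030 genes of at least 100 TPM in library 1 (−0.79 and 5.02). Both lower quartiles had to exceed 1 to exclude it, which held for library 1 alone, so it stays open; this test replaced one on genes chosen by library 2 (median −2.79 in library 1), where the choice itself favours a negative ratio. Pig RNA filling the libraries would raise pig matches with the unmatched share, by 0.94 in library 1, but their median log2 ratio was −0.19 (upper quartile 0.03), which argues against it. Under one shared source of unmatched transcripts, these genes would rank alike in libraries 1 and 3. Their Spearman correlation was 0.570 across genes, which are not independent replicates, against −0.12 and −0.08 with library 2. The genes were chosen by their highest value in these same libraries, which can itself lower the correlations with library 2. Over all genes the correlation of libraries 1 and 3 was 0.571, and those with library 2 were 0.423 and 0.296. The test therefore does not single out unmatched genes, and a shared source stays open. Neither its nature nor a biological explanation was tested.

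Microsporidian matches were higher in males, with 21 of 132 tested genes called higher and 0 lower. Scaling of the libraries was argued against, since their median log2 fold change was 1.63 before and 1.41 after quantile normalization (quartiles 1.14 and 1.70), although only 6 were then called. Among males, 90.9% of the genes were lowest in male library 2, against 25.1% of all tested genes. Their summed share was also lowest there (0.178%, against 0.373% and 0.404% in male libraries 1 and 3), so this outcome was largely set. It shows that the genes moved together, which genes that vary together for any reason would also do. One other organism in the libraries therefore stays open. Exposure that goes with sex cannot be told apart from a difference between the insects sampled: the summed TPM was 763 ± 111 in females and 3011 ± 1178 in males (SD, n = 3 each), with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 allow. Without these genes 370 genes differed between the sexes.

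Most genes were above 0 in one species only. Contigs of one gene kept apart by species are left undecided by the share of such genes in a component with a gene of the other species, 54.2% against 63.6% to 64.6% in 100 shuffles. A share below the shuffles was set to exclude them, which was wrong, since contigs that differ enough to be kept apart can also fall into separate components. If genes that the other species lacks were the whole cause, their annotation was predicted to be mostly missing there. Of 10598 such genes with a named product, 39.0% shared their annotation text with a gene above 0 in the other species. Several assembled genes can carry the same text, so a gene that the other species lacks can share it with a related gene there. No rate of sharing among other genes was computed, so this test cannot decide either. How far genes that the other species lacks account for the pattern is left open.

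Groups of 3 against 3 make 10 splits, too few for a share under 0.05. In the sex comparison 1 of 10 splits gave as many genes, the real one with 415, and the highest of the others gave 0. In the species comparison it was also 1 of 10, with 18127 genes and 9 in the highest of the others.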
